A study of Danio rerio with 18 samples.

How the data were processed

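Zebrafish larvae were exposed in beakers to nitroguanidine (NQ), an energetic compound used in munitions, for 96 h, and gene expression in whole larvae was measured on Agilent one-colour arrays. The 18 arrays comprised 6 controls and 4 arrays each at measured concentrations of 5.5 mg/L, 45.6 mg/L and 90.4 mg/L. Per the labels, each beaker held 8 larvae in 250 ml of water and RNA came from 4 whole fish per replicate. The fish were fed before the start and at 48 h. RNA was accepted above an integrity number of 7, and 600 ng of total RNA was labelled with Cy3. The labels list further concentrations for the exposure experiment, which are not analysed here. The times of day at which beakers were sampled are not stated.

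Per the file headers, the scans were quantified with Agilent Feature Extraction 10.7.3.1, which gave each spot a background-subtracted processed signal, an intensity in arbitrary units with spatial detrending and without normalization between arrays. The same deposited files gave the raw spot intensity, the local background and marks for outlier spots and for spots well above background. The deposited value table held log2 values per probe, and no label states how they were made. When compared with the scanner values it matched the processed signal on the log2 scale after each array's 75th percentile and each probe's median over the 18 arrays had been subtracted. The correlation with values made that way was 1 for every array, and 100% of the values lay within 0.1.

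Each array held 62976 spots, of which 1319 were control spots. The other 61657 belonged to 43603 probes. Over all arrays 685 spots marked as outliers were left out, and 0 spots were saturated. The processed signal was transformed to log2, spots of a probe were averaged, and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on at least 4 of the 18 arrays, the size of the smallest group, which left 35439 probes. Gene symbols came from a current RefSeq gene table through the accessions in the files, and 30147 probes for 15370 genes carried a symbol that is not a placeholder. Another 10908 probes kept the name in the file. Probe coordinates are those of the file headers (assembly Zv9). The array number limits the precision of every comparison.

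Groups were compared with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, empirical Bayes moderation and two-sided tests. Benjamini-Hochberg adjustment was made over all kept probes, and a probe passed at an adjusted p below 0.05. The comparisons were each concentration against control, the concentrations against each other, an F test of any difference among the 4 groups, and a linear trend on measured concentration. The p-values measure the spread between beakers, which per the labels are the replicates. Tables were read with the R package data.table (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

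The comparisons, the 32 gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. A gene was represented by its kept probe of highest mean signal. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those that passed. Where fewer than 10 passed in a direction all of them are named, and the genes of lowest p fill up to 5, given as values that did not pass. For each list described, up to 4 members of lowest p are named, and for the F test and the trend the 5 genes of lowest p. Any member of the lists of Nrf2 targets and of antioxidant enzymes may be named, because the series title names oxidative stress.

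Gene lists were tested against all other genes with limma's camera, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with limma's fry, which tests whether the genes of a list move on balance one way. The 96 tests, 32 lists in 3 comparisons, were adjusted together for each method. Counts of members are given over all probes and adjusted over the list alone. Some genes stand in several lists. The slides were taken into account as an alternative, since all 4 slides held 3 of the 4 groups and only slide 4 held both a control and an array at 5.5 mg/L.

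The steps were tested on simulated data made from the real probes' means and spreads, with 200 probes changed per comparison. Of the 50 probes changed 2-fold, 32% were recovered at 5.5 mg/L, 54% at 45.6 mg/L and 56% at 90.4 mg/L, among 35365 probes. Of those changed 4-fold, 90%, 92% and 98% were recovered. Calls among unchanged probes numbered 5, 15 and 17. A shift of 0.5 (log2) added to 1 list at 45.6 mg/L was found as 0.53, and 0 of 95 other list tests passed. The simulated probes varied independently, so this does not show how the list tests behave where genes of a list correlate. In the real data the estimated correlation reached 0.605, in cell cycle and DNA replication.

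The alternatives were normexp background correction, quantile and median scaling, the deposited value table, other filters, spots marked as outliers kept, slide as a fixed or random block, each slide alone, replicate number as a block, 2 groups at a time, other settings of the moderation, a 1.5-fold minimum, the rank of concentration, estimated inter-gene correlation, the mean over all probes of a gene for the lists, and leaving out each array. After the data had been seen, a run without the 5 arrays of noisiest spots and a run with arrays weighted by their residual spread were added. For the correlation of changes between concentrations, 20 simulations of unchanged groups against the same controls and 100 draws of resampled arrays were made. Groupings of the arrays other than the real one were run as well, up to 100 for each comparison.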

Results

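The data comprise 18 arrays of whole zebrafish larvae after 96 h in NQ, with 6 control beakers and 4 beakers at each of 3 concentrations, 5.5 mg/L, 45.6 mg/L and 90.4 mg/L. Between 69.1% and 83.9% of the probes were well above background on each array, and the 75th percentile of the signal lay between 291.6 and 617.9 intensity units. Pearson correlations across probes were 0.954 to 0.984 between arrays of the same group and 0.940 to 0.982 between arrays of different groups. Probes are not independent replicates. The series title names oxidative stress, and the comparisons address which genes differ from unexposed larvae at each concentration of the parent compound and whether the responses follow the concentration.

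At 5.5 mg/L 6 of 24 measured genes of the glucocorticoid list fell and 1 rose, and of 35 genes of the circadian clock 5 rose and 4 fell. The largest fall was in fkbp5, a glucocorticoid-inducible co-chaperone of the hormone's receptor, which changed by -3.82 ± 0.56 (log2, SE, n = 4 against 6, limma adjusted p = 0.00683). On 3 of the 4 exposed arrays fkbp5 was well above background, and without replicate 2, its lowest array, the change was -3.23. Its probe lies on chromosome 6 from 41046222 to 41046281. The transcription factor klf9, another glucocorticoid target, changed by -3.24 ± 0.56 (adjusted p = 0.0142), or -2.62 without replicate 2 and -3.88 without replicate 3. When adjusted over the list alone, 1 gene of glucocorticoid and stress-hormone response rose and 9 fell. Further members that fell were cebpd (-1.28), a transcription factor, and igfbp1a (-1.33), a binding protein of insulin-like growth factors. The list's median change was -0.49 (camera adjusted p = 7.31e-08), with an adjusted p = 0.227 with an estimated correlation and a fry adjusted p of 0.0135. With slide as a block the median was -0.40, and on slide 4 alone it was -0.20.

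In the clock list 14 genes rose and 8 fell at 5.5 mg/L when adjusted over the list alone. The clock repressor ciartb rose by 1.53 ± 0.18 (adjusted p = 0.00501), and the clock-controlled transcription factor dbpa rose by 1.02 ± 0.19. The clock activator bmal1a fell by 0.78, and the transcription factors nfil3-5 and nfil3 changed by -1.64 and -1.05. Because members moved both ways, the list's median was 0.22 with a camera adjusted p of 0.0963, and the median was 0.13 with slide as a block and 0.17 on slide 4. The nuclear receptor rorcb, whose family acts in the clock and in immune cells, changed by -1.90 ± 0.28.

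**Figure D1:**
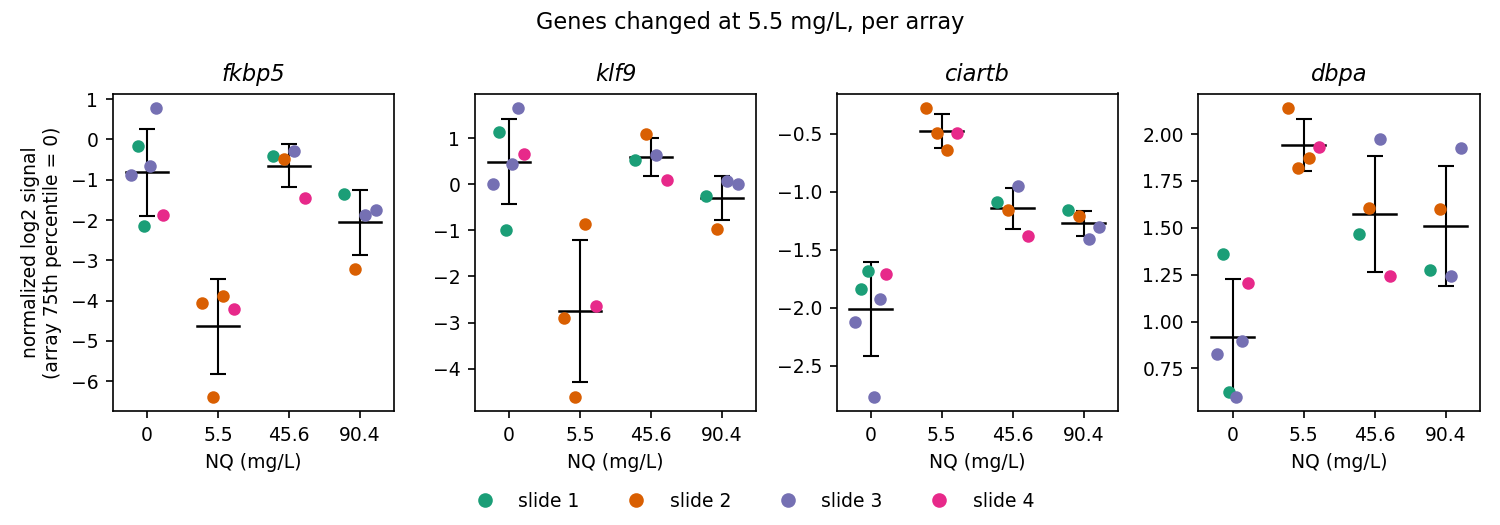
Normalized log2 signal of fkbp5, klf9, ciartb and dbpa on each of the 18 arrays, by measured NQ concentration in mg/L. Points are arrays coloured by slide, and bars give the group mean and SD; at 5.5 mg/L all 4 arrays lie outside the range of the controls for fkbp5, ciartb and dbpa, and 3 of the 4 do for klf9.

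At 5.5 mg/L 0 of the 37 measured genes of p53 and DNA damage response rose and 3 fell, and 7 fell when adjusted over the list alone. These were pmaip1 (-1.53), which promotes apoptosis, btg2 (-1.28), which restrains proliferation, and gadd45ba (-1.65), a growth arrest gene, whereas gadd45ab had a change of -0.74 that did not pass. The median of the list was -0.28 (camera adjusted p = 9.42e-07, adjusted p = 0.0333 with an estimated correlation, fry adjusted p = 0.000941). It was -0.28 with slide as a block and -0.10 on slide 4. Among the 34 genes of the unfolded protein response 3 fell, namely trib3 (-1.36), atf3 (-2.03) and ppp1r15a (-1.08), and 1 rose and 4 fell when adjusted over the list alone. Their median was 0.08 and their mean -0.05, with a camera adjusted p of 0.808. Of 42 hypoxia response genes 4 fell, ndrg1b (-1.15), hif1al (-1.28), igfbp1a (-1.33) and igfbp1b (-1.76), and 2 rose and 6 fell when adjusted over the list alone. The median there was 0.06, the mean -0.07 and the camera adjusted p 0.837. The immediate-early gene fosab changed by -1.80 ± 0.38 and the cyclin-dependent kinase inhibitor cdkn1d by -1.93 ± 0.31.

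Of 50 genes of acute phase and innate immunity 4 fell at 5.5 mg/L, and 3 rose and 17 fell when adjusted over the list alone. The iron-regulating peptide hormone gene hamp changed by -3.10 ± 0.57 (adjusted p = 0.0200), the transcription factor cebpb by -1.50, the complement component c7b by -1.30 and the cytokine signalling inhibitor socs3a by -1.57. The median was -0.30 (camera adjusted p = 0.000403, adjusted p = 0.447 with an estimated correlation, fry adjusted p = 0.0881), -0.19 with slide as a block and 0.04 on slide 4. Of 43 genes of proteasome and ubiquitin 0 rose and 0 fell over all probes, although 28 were lower when adjusted over the list alone. The values of lowest p were -0.74 for psmc5, -0.93 for psmd11b, -0.70 for psmb7 and -0.60 for psma6b, all subunits of the proteasome. That list's median was -0.48 (camera adjusted p = 6.36e-20, adjusted p = 0.227 with an estimated correlation, fry adjusted p = 0.0147). It was -0.63 with slide as a block and -0.76 on slide 4.

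Markers of liver, intestine and nervous system were higher on balance at 5.5 mg/L (fry adjusted p = 0.0337, 0.00504 and 0.00913). Of 62 genes of liver plasma proteins 1 rose, cyp8b1.1 (2.46-fold, SE 0.27 on the log2 scale), a sterol hydroxylase of bile acid synthesis, and 8 rose and 1 fell when adjusted over the list alone. Their median was 0.41 (camera adjusted p = 1.21e-08, adjusted p = 0.312 with an estimated correlation), 0.30 with slide as a block and 0.41 on slide 4. Of 49 intestine markers 1 rose, the chitinase chia.3 (0.87), and 9 rose when adjusted over the list alone, while ace (1.11) and alpi.2 (1.25) did not pass. Their median was 0.34 (camera adjusted p = 9.32e-08, adjusted p = 0.123 with an estimated correlation), 0.30 with slide as a block and 0.45 on slide 4. Among 57 neuron and glia markers 0 passed and 6 were higher when adjusted over the list alone, with values of 0.77 for slc17a6a and 0.72 for gap43. The median was 0.27 (camera adjusted p = 5.09e-06, adjusted p = 0.154 with an estimated correlation), 0.30 with slide as a block and 0.24 on slide 4. The ubiquitin ligase trim63a, which acts in muscle atrophy, changed by -1.79 ± 0.30, and was the 1 gene of 85 of skeletal muscle to pass. The median of that list was 0.17 (camera adjusted p = 7.81e-05, adjusted p = 0.434 with an estimated correlation, fry adjusted p = 0.0524), 0.16 with slide as a block, where the list no longer passed (camera adjusted p = 0.09), and 0.33 on slide 4.

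Other genes with large rises at 5.5 mg/L were the scaffold protein gene nherf4b (1.47), the lens crystallin crygm2f (1.35), the centrosomal gene nin (1.23), sobpa (1.04), the connexin gja13.1 (1.03), the guanylate cyclase activator guca1g (0.99) and the acid-sensing ion channel asic2 (0.96). Large falls were also found in the phospholipid transfer protein gene pltp (-2.17) and the small GTPase gene arf4b (-1.83). Of the genes named as falling, klf9, hamp, rorcb and pmaip1 were well above background on 3 of the 4 exposed arrays. Among those that rose, nin was on 2 and sobpa on 3 of the 6 control arrays.

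In total 163 of 35439 probes passed at 5.5 mg/L, 40 higher and 123 lower, for 23 and 78 named genes. At an unadjusted p below 0.05 the numbers were near balance, 2392 higher and 2334 lower. The count fell to 0 with slide as a fixed block (4726 probes had an unadjusted p below 0.05 without the block). There fkbp5 had a change of -2.89 (adjusted p = 0.258) and ciartb of 1.49 (adjusted p = 0.108). With slide as a random block it rose to 256, at an estimated within-slide correlation of -0.0505. A negative correlation does not stand for a shared slide difference, so this rise does not show one removed. The count was 56 without the 5.5 mg/L replicate 1, 58 without replicate 2, 87 without replicate 3, 61 without replicate 4, 106 without control replicate 4, 95 without control replicate 5 and 50 without the 5 arrays of noisiest spots. With arrays weighted by their residual spread, a run added after the data had been seen, it was 1304.

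At 45.6 mg/L genes of the interferon response rose together. Of the 33 measured members 15 rose and 0 fell, and 19 rose when adjusted over the list alone. The antiviral GTPase genes mxb and mxe rose by 5.96 ± 0.74 and 5.48 ± 0.41 (log2, SE, n = 4 against 6, limma adjusted p = 0.000175 and 2.72e-06). For mxb 1 of the 6 control arrays was well above background, and without that array, replicate 1, none was, so that the rise was then at least 95.9-fold. The ubiquitin-like modifier isg15 rose by 4.88 ± 0.45 and the antiviral enzyme rsad2 by 4.13 ± 0.36. No control array was well above background for mxe or rsad2, so that these rises were at least 41.4-fold and at least 17.4-fold. Such bounds, here and below, allow for dim control signals only and not for the spread between arrays. Without the 45.6 mg/L replicate 2 the changes of mxe and rsad2 were 5.15 and 3.84 (log2). The probes of mxe and rsad2 lie on chromosome 9 from 33865929 to 33865988 and on chromosome 17 from 35526722 to 35526781. The transcription factors stat1b and irf7, which carry the interferon signal, rose by 3.68 ± 0.30 and 2.84 ± 0.24. The other genes with the largest rises were the ubiquitin ligases herc56.3 (4.96) and herc56.4 (3.93), the interferon-inducible genes ifi27.2 (4.65), ifi27.6 (4.15) and ifit8 (4.46), and the antiviral gene mxa (4.05). The change of ifit8 was 5.16 without the 45.6 mg/L replicate 4, and 2 of 6 control arrays were well above background for it. For herc56.3 only control replicate 4 was, and without that array the rise was at least 38.7-fold, while mxa and herc56.4 were well above background on 3 of the 6 control arrays. The median of the list rose by 1.06 (camera adjusted p = 3.5e-78, adjusted p = 0.000377 with an estimated correlation, fry adjusted p = 2.05e-06). It was 1.01 with slide as a block, 1.66 within slide 1, 0.74 within slide 3 and 1.80 within slide 4.

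**Figure D2:**
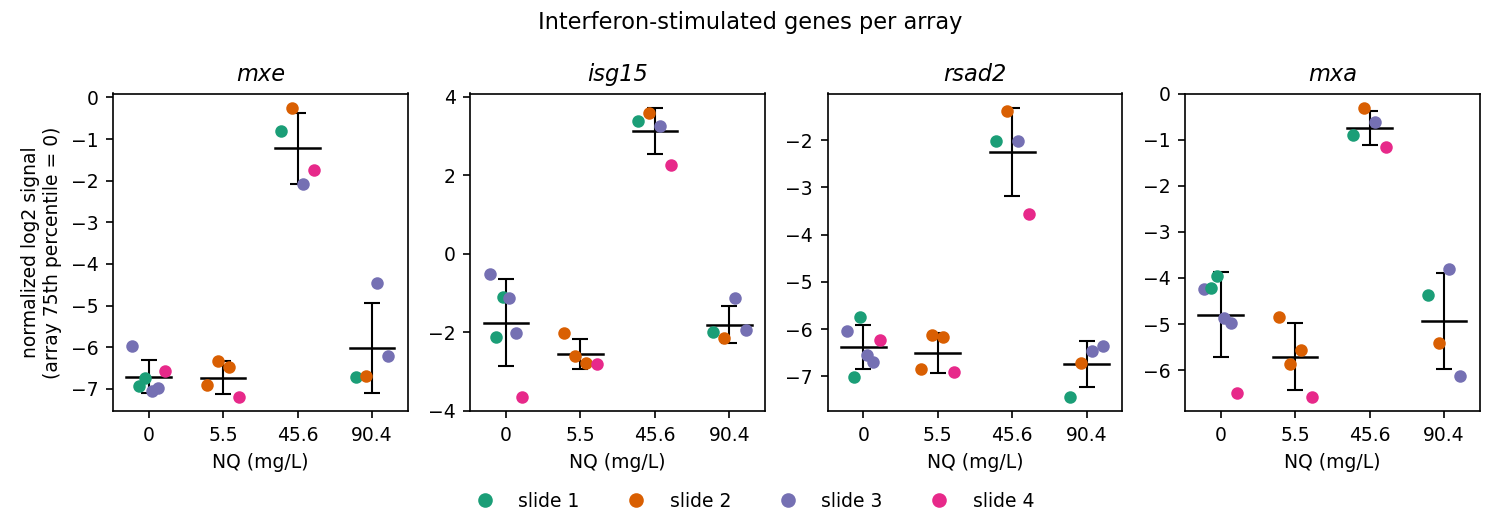
Normalized log2 signal of mxe, isg15, rsad2 and mxa on each of the 18 arrays, by measured NQ concentration in mg/L. Points are arrays coloured by slide, and bars give the group mean and SD; all 4 arrays at 45.6 mg/L lie above all 14 other arrays for each gene.

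Outside the interferon list, the chemokine ccl19a.1 rose by 2.26 ± 0.40 at 45.6 mg/L and was the 1 gene of 50 of acute phase and innate immunity to pass, and the apolipoprotein apoa4a rose by 2.32 ± 0.44. In the clock list ciartb rose by 0.87 ± 0.18, the 1 member to pass of 35, with 5 higher and 6 lower when adjusted over the list alone and a median of 0.07 (camera adjusted p = 0.521). Of 59 genes of photoreceptors and phototransduction 1 fell, the green cone opsin opn1mw1 (-1.02 ± 0.20), and 5 fell when adjusted over the list alone, whereas the opsins opn1lw2 (-1.44) and opn1sw2 (-0.67) did not pass over all probes. The median of that list was -0.24 (camera adjusted p = 7.03e-05, adjusted p = 0.647 with an estimated correlation), -0.22 with slide as a block, and -0.09, -0.30 and -0.61 within slides 1, 3 and 4. The nuclear receptor rorcb changed by -1.87 ± 0.28, the trehalose-cleaving enzyme treh by -1.04, the zinc finger gene zbtb4 by -0.80 and fam219b by -0.78.

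In total 170 probes passed at 45.6 mg/L, 153 higher and 17 lower, for 61 and 8 named genes. The larger share of rises holds only for these probes, since at an unadjusted p below 0.05 there were 1162 higher and 2019 lower, with a median of -0.06 over all probes. The count was 140 with slide as a fixed block, and within a single slide, where 1 array at 45.6 mg/L was compared, it was 0 on slide 1 and 4 on slide 3.

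At 90.4 mg/L 1 of 35439 probes passed, a probe without a gene name that was lower (-3.17, limma adjusted p = 0.0111), chosen for mention after its value was seen. At an unadjusted p below 0.05 there were 2623 probes, where chance gives 1772. The genes of lowest p did not pass. They were asic2 (1.14), chia.3 (0.73), pik3r6 (1.22), ciartb (0.74) and znf750 (0.99) among higher values, and atf3 (-1.85), slc25a25a (-0.98), gpx3 (-1.08), btg2 (-1.04) and eya3 (-1.05) among lower ones. Over the lists 6 camera tests passed at the preset correlation and 0 with an estimated one. The largest of these medians were -0.30 in the interferon response (camera adjusted p = 0.0400, adjusted p = 0.679 with an estimated correlation) and -0.26 in cell cycle and DNA replication (camera adjusted p = 7.03e-05, adjusted p = 0.776 with an estimated correlation). With slide as a block they were -0.38 and -0.23, and with normexp background correction the interferon median turned to 0.025. The cell cycle median was -0.82 within slide 1 and -0.04 within slide 3. Without the 5 arrays of noisiest spots the interferon median was -0.18 and the list did not pass (camera adjusted p = 0.0629). The count of probes was 0 without replicate 1, 2 or 4 at 90.4 mg/L, 3 without control replicate 3, 3 without the 45.6 mg/L replicate 2 and 4 without the 45.6 mg/L replicate 4.

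For oxidative stress, which the series title names, the list of Nrf2 targets and glutathione synthesis had 34 measured genes. Against control 0 of them passed limma over all probes at any concentration. Between 45.6 and 5.5 mg/L 1 was higher and 1 lower at 45.6 mg/L. The list's median change against control was 0.07 at 5.5 mg/L, 0.04 at 45.6 mg/L and 0.04 at 90.4 mg/L (camera adjusted p = 0.870, 0.566 and 0.308). With slide as a block the medians were 0.17, 0.075 and 0.02. On slide 4 alone they were 0.24 at 5.5 mg/L and 0.156 at 45.6 mg/L, values without a test. Within slides 1 and 3 the median at 45.6 mg/L was -0.058 and 0.056. When adjusted over the list alone 1 rose and 1 fell at 5.5 mg/L, the glutathione-cleaving enzyme ggt1b (2.14-fold, SE 0.31 on the log2 scale) and the heme oxygenase hmox1a (-0.85 ± 0.24), and 0 passed at the other concentrations. Of 34 antioxidant enzymes the uncoupling protein ucp2 fell at 5.5 mg/L (-1.05 ± 0.19, adjusted p = 0.0200). At 45.6 and 90.4 mg/L 0 passed against control over all probes. Between 45.6 and 5.5 mg/L 1 was higher and 1 lower at 45.6 mg/L, and 1 was lower at 90.4 than at 5.5 mg/L. The medians of the list of antioxidant enzymes were -0.05, 0.02 and 0.05 (camera adjusted p = 0.581, 0.888 and 0.913). A further fry test asked whether a list's genes change in either direction, without comparison to other genes. Its adjusted p were 0.0505, 0.28 and 0.0317 for the antioxidant enzymes, and 0.0728, 0.0601 and 0.214 for the Nrf2 list. The glutathione peroxidase gpx3 had a value of -1.08 ± 0.22 at 90.4 mg/L that passed when adjusted over the list alone and not over all probes (adjusted p = 0.312). In the F test of any difference among the groups gpx3 did pass over all probes (adjusted p = 0.00878). The 19 glutathione S-transferases had medians of 0.10, 0.13 and 0.14, and 0 passed (camera adjusted p = 0.308, 0.389 and 0.0626 for the list). At 90.4 mg/L the list's camera adjusted p was 0.662 with an estimated correlation, 0.12 with slide as a block, and 0.00468 without the 5 arrays of noisiest spots, where its median was 0.175.

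**Figure D3:**
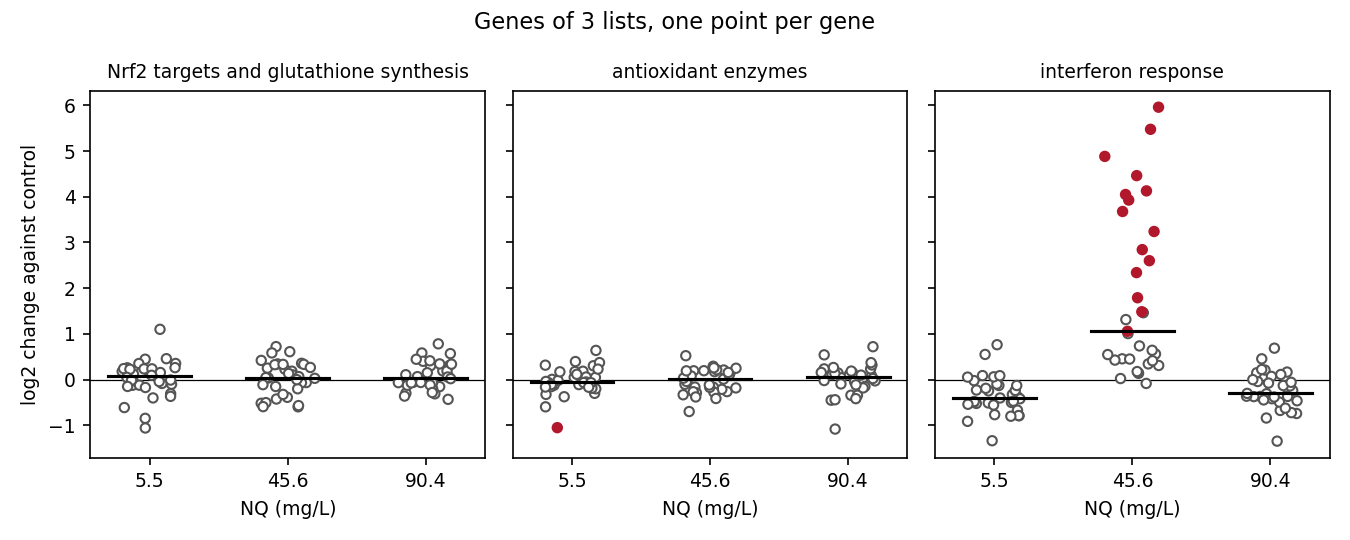
Log2 change against control of each measured gene of 3 lists at each NQ concentration in mg/L. Each point is a gene, filled where it passed over all probes, and the bar is the list's median; the Nrf2 medians are 0.07, 0.04 and 0.04, and the interferon median is 1.06 at 45.6 mg/L.

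Interferon and proteasome genes also differed between the concentrations. Between 45.6 and 5.5 mg/L 1337 probes differed, 763 higher and 574 lower at 45.6 mg/L. That balance depended on scaling, with 958 higher and 318 lower under median scaling and 896 and 462 under quantile scaling, and at an unadjusted p below 0.05 it was the opposite, 3060 higher and 4692 lower. Of the 33 interferon genes 18 were higher at 45.6 than at 5.5 mg/L, and 18 were lower at 90.4 than at 45.6 mg/L, where the median of the list was -1.37. The proteasome list had 15 of 43 genes higher at 45.6 than at 5.5 mg/L and 0 lower, with a median of 0.59, or 0.73 with slide as a block. Of 37 genes of p53 and DNA damage response 6 were higher at 45.6 than at 5.5 mg/L, and of 24 of glucocorticoid and stress-hormone response 4 were. Of the 57 neuron and glia markers 5 were lower. The p53 list shares 1 gene, isg15, with the interferon list, and the glucocorticoid list also shares 1. Their counts may therefore include interferon genes. Between 90.4 and 5.5 mg/L 68 probes differed, 52 higher and 16 lower, and between 90.4 and 45.6 mg/L 200 did, 32 higher and 168 lower. At an unadjusted p below 0.05 the last balance was also the opposite, 2445 higher and 1673 lower. With slide as a fixed block the counts were 393, 0 and 163 (5517 probes had an unadjusted p below 0.05 between 90.4 and 5.5 mg/L without the block). The count between 45.6 and 5.5 mg/L was 624 without the 5.5 mg/L replicate 2, 521 without replicate 3, 567 without replicate 4, 805 without the 45.6 mg/L replicate 1 and 838 without its replicate 2. The count between 90.4 and 5.5 mg/L was 32 without control replicate 1, 20 without the 5.5 mg/L replicate 1 and 0 without its replicate 2, 3 or 4. It was 109 without the 45.6 mg/L replicate 4, 0 without the 90.4 mg/L replicate 1 or 4, 1 without its replicate 2 and 115 without its replicate 3.

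The F test found 552 probes that differed among the 4 groups. Of these, 291 had their highest mean at 45.6 mg/L and 330 their lowest at 5.5 mg/L. The 5 genes of lowest p were stat1b, irf7, mxe, ifi27.4 and rsad2, all interferon-inducible, with adjusted p from 1.91e-06 to 4.44e-06. With slide as a block the count was 220, and it was 303, 302 and 307 without the 5.5 mg/L replicates 2, 3 and 4. A linear trend with concentration passed in 1 probe without a gene name, which fell (adjusted p = 0.0246), against 3250 at an unadjusted p below 0.05. That count became 0 without control replicate 1, 3 or 6, the 5.5 mg/L replicate 2, the 45.6 mg/L replicate 1, or the 90.4 mg/L replicate 2 or 4. It was 2 without control replicate 2 or the 45.6 mg/L replicate 4, and 4 without the 90.4 mg/L replicate 1. The named genes of lowest p did not pass. For gpx3 the slope was -0.14 (log2 per 10 mg/L, adjusted p = 0.118), and for the receptor kinase tyro3, pr2y4l, the laminin chain lamc1 and fam49al the adjusted p was 0.334.

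The 3 comparisons share their 6 controls, which alone makes changes correlate across probes. Between 5.5 and 45.6 mg/L the correlation was 0.08, where simulated unchanged groups gave 0.399, and the covariance was 0.013, where they gave 0.0334. Between 5.5 and 90.4 mg/L the correlation was 0.295 and the covariance 0.0393 (simulated 0.399 and 0.0335), and between 45.6 and 90.4 mg/L they were 0.234 and 0.0309 (simulated 0.401 and 0.0336). Resampled arrays gave correlations at or under the observed values in 6, 25 and 17 of 100 draws, so that these correlations lie within the spread between arrays. With the controls split 3 and 3, the median correlations were -0.067, 0.052 and -0.005. Of the probes that passed, 1 was higher at both 5.5 and 45.6 mg/L, where independent calls give 0.17, and 1 was lower at both, where they give 0.06. Shared controls can raise such overlaps without a common response, and their size under shared controls was not simulated. The 1 probe that passed at 90.4 mg/L was also lower at 5.5 mg/L.

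**Figure D4:**
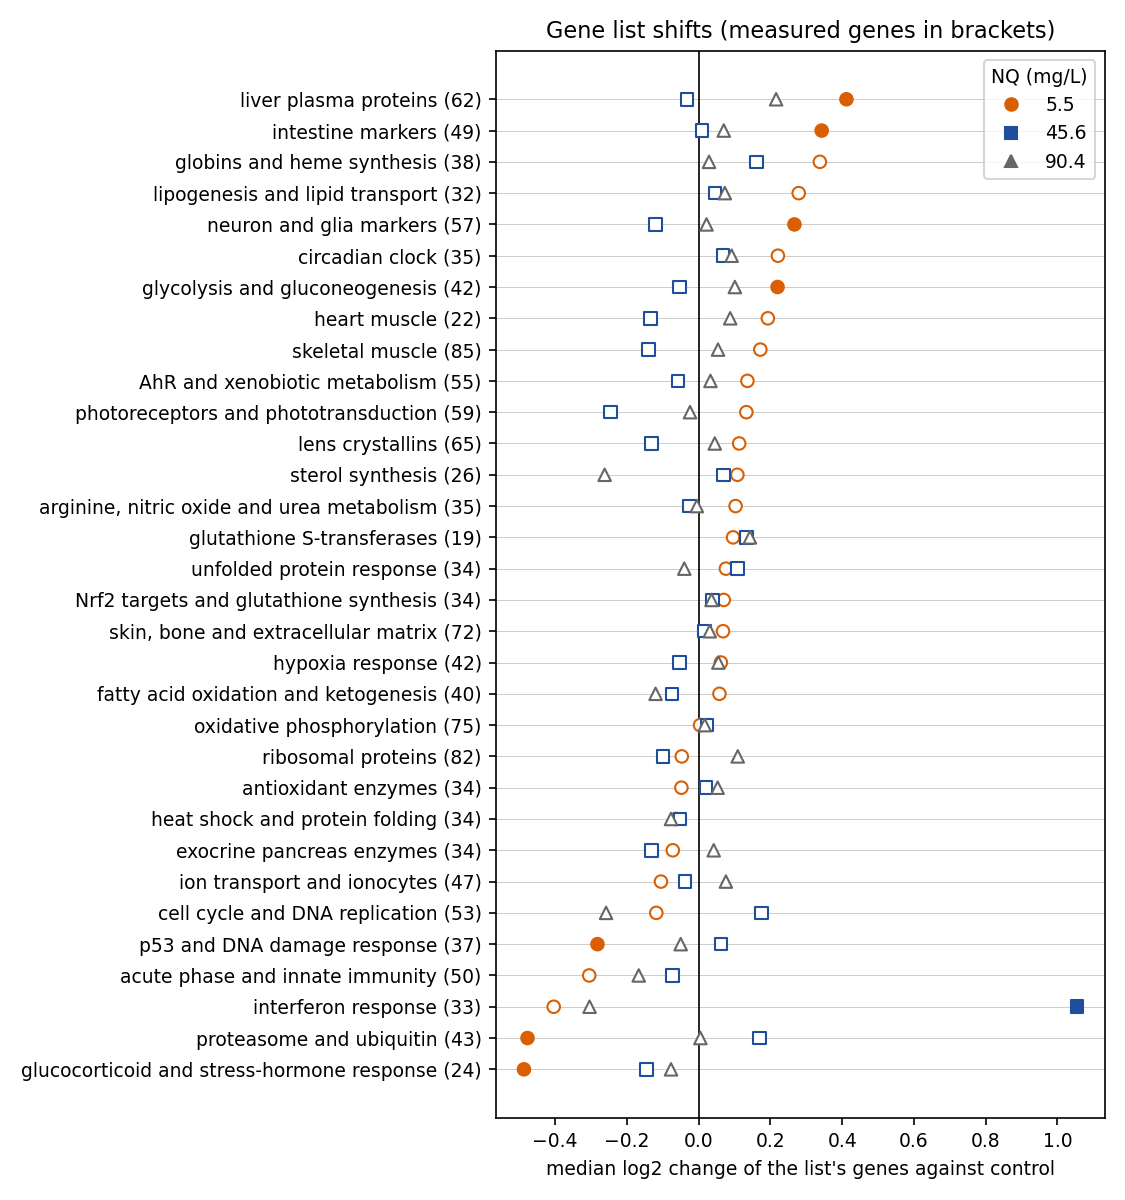
Median log2 change against control of each of the 32 gene lists, with the number of measured genes in brackets, at 5.5 mg/L, 45.6 mg/L and 90.4 mg/L NQ. Filled symbols mark a fry adjusted p below 0.05; the interferon response at 45.6 mg/L lies at 1.06, and the lowest medians at 5.5 mg/L are -0.49 for the glucocorticoid list and -0.48 for the proteasome list.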

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

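The tests of the interferon genes for slide, for a single array and for a rise with concentration, the test of sampling time, the comparison on slide 4, the test of noisy arrays and the look at which arrays a trend grouping set highest were chosen after the result was seen, and the counts over other groupings of the arrays were planned.

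The rise of interferon response genes at 45.6 mg/L stood apart from the other exposed groups. A difference between slides as the whole source is argued against by the within-slide shifts, the lowest of which was 0.739, against an SD of 0.218 between control arrays. A single aberrant array is argued against by the 4 arrays at 45.6 mg/L that all lay above the 14 others. A steady rise with NQ concentration is argued against by the median difference of -1.373 between 90.4 and 45.6 mg/L. What stays open is an effect of NQ at this concentration alone, or an infection or other difference in the housing of these fish, which may give such a response, and neither was tested. Of 100 groupings of these arrays, drawn from 210 possible, 1, the real one, gave a median shift as large (1.055, next highest 1.044). For the count of probes 1 did as well (170, next highest 106). Such a share argues against chance for both and cannot exclude it, as 1 is the smallest number possible. The other groupings mix arrays at 45.6 mg/L with controls, so the response itself enters their values. Over them the median absolute shift was 0.419 and the median count of probes 0.

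The falls in stress-hormone genes and the shifts in clock genes at 5.5 mg/L rest on 4 arrays, 3 of them on slide 2, which held no control. Slide 2 as the source is argued against, though only by its 1 array at 45.6 mg/L and its 1 array at 90.4 mg/L. These differed from their groups elsewhere by a median share of -0.012 of the change (bootstrap interval -0.076 to 0.021). The interval came from resampling the 163 called probes, so it does not measure the spread between arrays. Of 57 probes called without slide 4, 56 moved the same way on slide 4, by a median of 0.942, against a median of 1.619 without slide 4. A difference in the time of sampling is a candidate explanation that stays open, because the 16 repressor and output genes and the 6 activator genes of the clock moved apart by 1.344 at 5.5 mg/L (exact permutation p = 0.00476, adjusted 0.0143, n = 4 against 6, control SD 0.376), and the labels give no sampling times with which to separate it from an effect of NQ. Of 100 groupings 1, the real one, gave as many probes (163, next highest 1). This argues against chance, cannot exclude it, and leaves sampling time untouched.

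The small count at 90.4 mg/L was weighed against noisy arrays. With arrays weighted by their residual spread 2 probes passed, so giving noisy arrays less weight did not bring a larger response to view. Weighting cannot restore the precision that noisy arrays lose. At 90.4 mg/L replicates 2 and 4 had median spot coefficients of variation of 16.24% and 33.3%. Noise as a part of the source therefore stays open. Of 100 groupings 10 gave as many probes as the real one (1, highest other 36), so that chance cannot be excluded. The grouping with 36 set 3 arrays of slide 1 and 1 of slide 2 against the rest. These were all arrays of this comparison on slides 1 and 2, and the rest lay on slides 3 and 4. The count of 36, against 1 for the real groups, thus goes with a difference between slides. That grouping was picked as the highest, so its count is not a test of slides. Between arrays of different groups, deviations from the group means had a median correlation of 0.016 on the same slide, against -0.013 otherwise. Pairs within a group were left out, so these correlations neither show nor exclude a difference between slides. With slide as a fixed block 0 passed. A weaker response, or none, at 90.4 mg/L stays open as the biological explanation, and could not be tested further.

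For the differences between concentrations 1 of 35 groupings, the real one, was as large in each case. That is the smallest share 35 groupings can give, so it argues against chance and cannot exclude it. The other groupings also mix the real groups, which widens the spread within them. The counts were 1337 between 45.6 and 5.5 mg/L, 68 between 90.4 and 5.5 mg/L and 200 between 90.4 and 45.6 mg/L, and the highest other was 1 each time. With slide as a fixed block the count between 90.4 and 5.5 mg/L was 0. For the F test 1 of 100 groupings was as large (552, highest other 131). For the trend 7 of 100 were (1, highest other 153), so that chance cannot be excluded. The grouping with 153 set 3 of the 4 arrays at 45.6 mg/L at the highest concentration, and 67 of its probes had passed at 45.6 mg/L against control, so that the response at 45.6 mg/L may account for part of that count. The number of gene lists that passed at the preset correlation was 14 at 5.5 mg/L, 8 at 45.6 mg/L and 6 at 90.4 mg/L. Groupings as large numbered 12, 58 and 59 of 100, with highest others of 18, 21 and 15, so that chance cannot be excluded for these 3 numbers. In each comparison 99 other groupings passed lists, with medians of 9, 8 and 6. A pass at the preset correlation alone is therefore weak evidence for any list, however small its adjusted p.

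In 126 groups of arrays searched for a single array far from the others 9 were found, where chance gives about 6.3. The spots of the 45.6 mg/L replicate 3 had a median coefficient of variation of 28.75%, against 6.14% to 7.48% in its group. The 90.4 mg/L replicate 1 had a 75th percentile of 596.9, against 291.6 to 343. The p53 list stood at -0.07 in the 90.4 mg/L replicate 4, against -0.134 to -0.128. The signal of fkbp5 was -6.389 in the 5.5 mg/L replicate 2, against -4.213 to -3.89. In the controls cdkn1d was 1.985 in replicate 5 (others 0.57 to 1.043), rorcb -2.947 in replicate 4 (others -2.001 to -1.746) and mxb -2.433 in replicate 1 (others -7.313 to -6.426). At 45.6 mg/L ifit8 was -3.492 in replicate 4 (others -0.784 to -0.581) and treh -1.354 in replicate 3 (others -0.569 to -0.428).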

How the results depend on the processing

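The runs without the 5 arrays of noisiest spots and with weighted arrays were chosen after seeing the data, and all others were planned. The cause was not tested for any change given here, except where fewer arrays or an added block leave fewer degrees of freedom. Depth is limited by signal over background, which between 69.1% and 83.9% of probes exceeded clearly.

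No named gene that passed turned direction under any alternative. The 41 named genes that passed at 5.5 mg/L all stayed past the threshold with quantile scaling, the deposited value table and the outlier spots kept, 39 did with normexp, 0 with slide as a fixed block and 12 without the 5 noisiest arrays. Of the 20 at 45.6 mg/L 19 stayed with normexp, 16 with slide as a fixed block and 14 without those arrays. Normexp moved the median of all probes at 90.4 mg/L to 0.115, and other scalings moved it to between 0.003 and 0.027.

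Counts over 1.5 times from those reported were as follows. With normexp 0 probes passed at 90.4 mg/L, 123 between 90.4 and 5.5 mg/L and 0 in the trend. Quantile scaling gave 5, 121 and 2. Median scaling gave 111 between 90.4 and 5.5 mg/L, and no filter gave 38. Probes above background on all 18 arrays gave 0 at 90.4 mg/L, 181 between 90.4 and 5.5 mg/L and 0 in the trend.

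Slide as a fixed block gave 0 at 5.5 mg/L, 0 at 90.4 mg/L, 393 between 45.6 and 5.5 mg/L, 0 between 90.4 and 5.5 mg/L, 220 in the F test and 0 in the trend, and the correlation of changes at 5.5 and 45.6 mg/L was 0.219. Slide as a random block, at an estimated within-slide correlation of -0.0505, gave 256 at 5.5 mg/L and 128 between 90.4 and 5.5 mg/L. Within slide 1 counts were 0 at 45.6 mg/L and 1 between 90.4 and 45.6 mg/L, within slide 2 they were 23 between 45.6 and 5.5 mg/L, 1 between 90.4 and 5.5 mg/L and 1 between 90.4 and 45.6 mg/L, and within slide 3 they were 4 at 45.6 mg/L, 0 at 90.4 mg/L and 0 between 90.4 and 45.6 mg/L. In slides with 1 array of a group, that array is assumed to vary like the other groups. Slide 4, with 1 array per group, gave values without a test.

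Replicate number as a block gave 36 at 5.5 mg/L, 105 at 45.6 mg/L, 5 at 90.4 mg/L, 840 between 45.6 and 5.5 mg/L, 5 between 90.4 and 5.5 mg/L, 290 in the F test and 0 in the trend, with Nrf2 medians of -0.008 at 45.6 mg/L and -0.006 at 90.4 mg/L and a correlation of 0.41 between 5.5 and 90.4 mg/L. The numbers do not pair the arrays. Deviations from the group means correlated between -0.209 and 0.242 in 24 pairs of equal number, 4 above 0.1, and 3 of 18 arrays matched their own number best.

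With 2 groups at a time counts were 0 at 90.4 mg/L, 366 between 45.6 and 5.5 mg/L, 0 between 90.4 and 5.5 mg/L and 112 between 90.4 and 45.6 mg/L. Moderation with trend and robust gave 248 at 5.5 mg/L, 2 at 90.4 mg/L, 180 between 90.4 and 5.5 mg/L and 0 in the trend, and the rank of concentration gave 0 in the trend. An estimated inter-gene correlation left 2 list tests. The probes between 45.6 and 5.5 mg/L were 765 higher and 753 lower when above background on all 18 arrays, 317 and 76 with slide as a fixed block, and 1491 and 1469 with weighted arrays.

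Without the 5 noisiest arrays counts were 50 at 5.5 mg/L, 0 at 90.4 mg/L, 1 between 90.4 and 5.5 mg/L, 88 between 90.4 and 45.6 mg/L, 265 in the F test and 0 in the trend. Weighted arrays gave 1304 at 5.5 mg/L, 2 at 90.4 mg/L, 2960 between 45.6 and 5.5 mg/L, 1093 between 90.4 and 5.5 mg/L and 2073 in the F test. The correlation of changes at 5.5 and 45.6 mg/L turned to -0.03 without the noisiest arrays and to -0.018 with weights.

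The Nrf2 median at 90.4 mg/L was -0.003 with quantile scaling and -0.058 within slide 1, at 45.6 mg/L -0.058 within slide 1, and at 5.5 mg/L -0.012 with probes above background on all arrays and -0.001 without the noisiest arrays.

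With each array left out in turn, counts ranged from 56 to 232 at 5.5 mg/L, 0 to 4 at 90.4 mg/L, 521 to 1648 between 45.6 and 5.5 mg/L, 0 to 115 between 90.4 and 5.5 mg/L, 302 to 650 in the F test and 0 to 4 in the trend. They stayed within 1.5 times at 45.6 mg/L (135 to 206), between 90.4 and 45.6 mg/L (158 to 224) and for list tests (23 to 35). Correlations ranged from -0.005, without the 5.5 mg/L replicate 1, to 0.148 (5.5 and 45.6 mg/L) and from 0.214 to 0.37 (5.5 and 90.4 mg/L). Nrf2 medians ranged from -0.02 to 0.13 at 45.6 mg/L and from -0.013 to 0.082 at 90.4 mg/L.

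Medians of lists that passed camera at the preset correlation turned sign in these cases. The interferon list at 90.4 mg/L stood at 0.025 with normexp. Within slide 1 at 45.6 mg/L the cell cycle list stood at -0.148, globins at -0.456 and the unfolded protein response at -0.198, and at 90.4 mg/L liver plasma proteins stood at -0.035 and ribosomal proteins at -0.007. Within slide 4 acute phase genes stood at 0.036 at 5.5 mg/L and skeletal muscle at 0.092 at 45.6 mg/L. At 45.6 mg/L the cell cycle list stood at -0.056 with replicate number as a block, and globins ranged from -0.086, without the 45.6 mg/L replicate 4, to 0.259 with each array left out in turn. Medians of lists that did not pass turned sign in further cases, such as at 5.5 mg/L the cell cycle list (0.024 with slide as a block), heat shock (0.016 without the noisiest arrays) and ribosomal proteins (0.029 without those arrays).

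Of the 28 list tests that passed at the preset correlation, 9 did not pass with slide as a fixed block. These were lipogenesis (0.0995), photoreceptors (0.312), lens crystallins (0.134) and skeletal muscle (0.09) at 5.5 mg/L, globins (0.0863), neuron and glia markers (0.168) and proteasome (0.0908) at 45.6 mg/L, and fatty acid oxidation (0.0863) and ribosomal proteins (0.396) at 90.4 mg/L. Without the noisiest arrays 3 did not pass, skeletal muscle at 45.6 mg/L (0.245) and fatty acid oxidation (0.34) and interferon response (0.0629) at 90.4 mg/L. The numbers lost, beside medians that turned sign, were 4 with normexp, 2 with quantile and 4 with median scaling, 1 with no filter, 3 with probes above background on all 18 arrays, 2 with slide as a random block, 5 with replicate number as a block, 8 with 2 groups at a time, 6 with the mean over all probes of a gene, 4 with weighted arrays, and 1 to 8 with each array left out in turn. Within slides 1 and 3, where 14 of these tests could be run, 5 and 10 were lost.

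Some lists passed camera only under an alternative. Without the noisiest arrays these were at 5.5 mg/L the circadian clock (camera adjusted p = 0.0297) and heart muscle (0.0153), and at 90.4 mg/L glutathione S-transferases (0.00468), p53 and DNA damage response (0.00864), glycolysis (0.0183), lipogenesis (0.0183), the circadian clock (0.0153) and intestine markers (0.00247). Sterol synthesis (0.0128) and ribosomal proteins (1.21e-05) at 5.5 mg/L and ribosomal proteins at 45.6 mg/L (0.0055) did with slide as a block.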

Other observations

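The comparison of clock arms and the count of opposite signs were chosen after the result was seen, and the list tests were planned.

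Several lists not yet described passed camera at 5.5 mg/L at the preset correlation with few members passing, and of these only glycolysis and gluconeogenesis also passed fry (adjusted p = 0.0337). Of 59 genes of photoreceptors and phototransduction 2 rose, guca1g and the mitochondrial creatine kinase ckmt2a (0.82), with a median of 0.13 (camera adjusted p = 0.0126, adjusted p = 0.748 with an estimated correlation). It was 0.02 with slide as a block, where the list did not pass (0.312). Of 65 lens crystallins 1 rose and the median was 0.11 (0.00553, 0.662 with an estimated correlation and 0.134 with slide as a block). Globins and heme synthesis (38 genes, 0 passed) had a median of 0.34 (0.000336, and 0.662 with an estimated correlation), glycolysis and gluconeogenesis (42 genes, 0 passed) one of 0.22 (0.00736, and 0.312), and lipogenesis and lipid transport (32 genes, 1 fell, pltp) one of 0.28 (0.0409, and 0.662). The lipogenesis median was 0.03 on slide 4, and its adjusted p was 0.0995 with slide as a block. The interferon list stood at -0.40 at 5.5 mg/L (0 of 33 passed, 0.00441, and 0.647 with an estimated correlation). In 3 more lists not yet described a member passed and the list did not pass camera. Of 55 genes of AhR and xenobiotic metabolism the transporter abcb4 rose by 0.82, with a median of 0.14 (camera adjusted p = 0.0881). Of 40 genes of fatty acid oxidation and ketogenesis the uncoupling protein ucp3 changed by -1.35, with a median of 0.06 and a mean of -0.01 (camera adjusted p = 0.941). Of 35 genes of arginine, nitric oxide and urea metabolism, pathways of guanidino compounds, 1 rose, ckmt2a, with a median of 0.10 (camera adjusted p = 0.209).

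At 45.6 mg/L cell cycle and DNA replication (median 0.17, 0 of 53 passed), proteasome and ubiquitin (0.17, 0 of 43), unfolded protein response (0.11, 0 of 34), globins and heme synthesis (0.16, 0 of 38), neuron and glia markers (-0.12, 0 of 57) and skeletal muscle (-0.14, 0 of 85) passed camera at the preset correlation only. With an estimated correlation their adjusted p were 0.776, 0.748, 0.679, 0.776, 0.647 and 0.718. Proteasome (0.0908), globins (0.0863) and neuron and glia markers (0.168) also did not pass with slide as a block, and skeletal muscle (0.245) did not without the 5 arrays of noisiest spots. The means of the globin list on the 4 arrays were -0.168, -0.255, 0.228 and 1.28, and its median was -0.086 without replicate 4 and -0.456 within slide 1. The cell cycle and unfolded protein response medians were also negative within slide 1 (-0.148 and -0.198), and the skeletal muscle median was 0.092 within slide 4. At 90.4 mg/L the same held for liver plasma proteins (0.22, 0 of 62), acute phase and innate immunity (-0.17, 0 of 50), ribosomal proteins (0.11, 0 of 82) and fatty acid oxidation and ketogenesis (-0.12, 0 of 40), with adjusted p of 0.662, 0.653, 0.905 and 0.647, and within slide 1 the liver and ribosomal medians were -0.035 and -0.007. Ribosomal proteins (0.396, median 0.057) and fatty acid oxidation (0.0863) did not pass with slide as a block, and fatty acid oxidation did not without the noisiest arrays (0.34). Of the 28 list tests that passed at the preset correlation 2 did with an estimated one, the interferon response at 45.6 mg/L and the p53 list at 5.5 mg/L. The lists of heat shock and protein folding, oxidative phosphorylation, sterol synthesis, heart muscle, exocrine pancreas enzymes, skin, bone and extracellular matrix, and ion transport and ionocytes passed camera in 0 of the 3 comparisons. Their medians at 5.5 mg/L were -0.06, 0.00, 0.11, 0.19, -0.07, 0.07 and -0.10.

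The arms of the clock also moved apart at the higher concentrations, by 0.569 at 45.6 mg/L (exact permutation p = 0.0286, adjusted 0.0333, n = 4 against 6) and by 0.562 at 90.4 mg/L (exact permutation p = 0.0333, adjusted 0.0333, n = 4 against 6). The difference between the arms lay above that of all controls on 4 of 4 arrays at 5.5 mg/L, 3 of 4 at 45.6 mg/L and 4 of 4 at 90.4 mg/L. The difference between 5.5 and 45.6 mg/L was 0.774 (exact permutation p = 0.0286, n = 4 against 4). This pattern was found and tested on the same arrays, so that a shift of all exposed beakers in sampling time may account for it as well as NQ, given the 1.344 at 5.5 mg/L.

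Of the 1337 probes that differed between 45.6 and 5.5 mg/L 1223, or 91.5%, had changes of opposite sign from control, against 50.9% over all probes. These probes were picked for that difference, so the share is not evidence of opposite responses.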
